A study of Homo sapiens with 8 samples.

How the data were processed

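RNA-seq was analysed from 8 libraries of 2D10 Jurkat cells, 4 untreated and 4 treated with SR4835 for 6 h. Groups and replicate numbers were taken from the sample titles, since the treatment tag of the labels is the same in all samples. The deposited table of each library gives, per the file headers, an expected count for each gene, which is an estimate that need not be whole. The deposited TPM values were scaled by the authors to transcript length and library total. FPKM values, also deposited, were not used here. A deposited table of log2 values holds, per its header, a regularised log transform of the counts made by the authors with DESeq2. Per the submitters' processing notes, the genome build was GRCh38 and the tools included FastQC 0.12.1, STAR 2.7.10b, featureCounts 2.0.6 and DESeq2 2.40.1, with no role given. The program behind the expected counts, the annotation release and the strand setting are not given in the sources used here.

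The viral gene names had another separator in untreated replicates 1 and 2 than in the other 6 tables and were brought to 1 spelling. Expected counts were rounded to whole numbers. Of 60692 genes in the tables, 58505 were placed by Ensembl identifier in GENCODE release 29 on GRCh38 or were viral, and class, genomic span and coordinates were taken from there. Depth was 31663276 to 43093932 counts per library. Counting error is not small for genes of few counts, such as ARC and EGR2 in untreated libraries. No pair of libraries was identical (highest correlation of log2 values 0.982), and all 8 were kept. Fragment length, estimated as length minus effective length of long genes, was 166 bases in treated replicate 1 and up to 218 bases in the others.

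Differential expression used edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test, TMM factors, filterByExpr, which left 16698 genes, group as the only term, and Benjamini-Hochberg adjusted p under 0.05, two-sided. The SE of a log2 fold change was its size divided by the square root of F. CPM values are TMM-scaled. The test was tried on simulated counts for treated against untreated over 16698 genes. There 80% of 50 genes raised 4-fold and 8% of 50 raised 2-fold were called, with 66% at a fold of 0.25 and 6% at a fold of 0.5. Of 85 calls, 4 were of unchanged genes. Only 200 genes were changed at fixed folds there, and fewer calls make the adjusted threshold stricter than in the real fit. The shares called therefore do not carry over to the real fit. A simulated shift of -0.5 in long genes, over 4933 genes, was recovered as -0.48.

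Before the data were examined, 26 gene lists with 770 entries were written from textbook knowledge, together with the tests and the naming rule. The lists cover DNA damage response, DNA replication, G2 and mitosis, transcriptional kinases, P-TEFb, immediate early genes, NF-kappaB targets, T cell activation, the T cell receptor, interferon-stimulated genes, heat shock, integrated stress response, p53 targets, apoptosis, polyadenylation, splicing, host repressors of HIV-1, cholesterol synthesis, histones, ribosomal proteins, mitochondrial genes, and markers of B, myeloid, NK, erythroid and epithelial cells. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a correlation of 0.01, with an estimated correlation, and with fry. The genes named were set by a rule, and 3 of the genes it takes are left out of the report. It takes CDK12, CDK13, CCNK, CDK9, CCNT1 and HEXIM1. It takes the 8 largest rises and 8 largest falls among protein-coding genes past the threshold with a mean of at least 100 reads and no overlap between groups. From each list it takes the 3 members with the smallest p in the direction of most of its calls and the 1 called member with the smallest p in the other direction, and a list with no call gives its median. HIV-1 genes lie outside the rule and were chosen after the data were seen.

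Values per library were compared by exact permutation tests in scipy 1.17.1, with 70 groupings for 4 against 4 and a smallest two-sided p of 0.0286. Alternatives fixed before the data were examined were RLE factors, scaling on ribosomal protein genes, no filter, at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, other thresholds and definitions, and leaving out each library. Added after seeing the data were limma on the deposited log2 values and fits without untreated replicates 1 and 2, without treated replicates 1 and 4, and without untreated replicate 1 and treated replicate 4.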

Results

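RNA was sequenced from 2D10 cells, a clone of the Jurkat T cell leukaemia line that carries a latent HIV-1 provirus. There were 8 libraries, 4 from untreated cells and 4 from cells given SR4835 for 6 h. The labels describe SR4835 as an inhibitor of CDK12 and cyclin K, which phosphorylate RNA polymerase II during elongation. Each library held between 31663276 and 43093932 expected counts. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Fold changes are positive where treated cells were higher, are given on the log2 scale ± SE, and carry adjusted p-values from edgeR's quasi-likelihood test.

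Treatment went with higher and lower levels of many genes. Of 16698 genes tested, 2019 were higher and 2469 lower in treated cells at an adjusted p under 0.05. Among the largest rises of protein-coding genes were the immediate early genes ARC and FOS and ID2, an inhibitor of helix-loop-helix factors. PTER, KRCC1 and PAQR8 had the largest falls among stable calls. The 4 treated and 4 untreated TMM-scaled values did not overlap for 28.6% of the genes tested, against an expected 2.86% over all groupings. Genes are not independent, so these shares do not exclude chance. The balance of rises and falls moved with the scaling. With RLE factors 2269 genes were higher and 2230 lower. With the cytosolic ribosomal protein genes as the reference, the median of all genes shifted by -0.999 on the log2 scale, and 243 genes were higher and 5113 lower. Other fits changed the test, filter or unit as well. On the deposited TPM values, log2(TPM + 1), limma gave 380 higher and 5286 lower, and on log2(TPM + 0.1) 400 and 5288. DESeq2, which tested 47029 genes, gave 3980 higher and 2874 lower. No gene called in both TMM scaling and any of these had the opposite direction. The number of changed genes, 4488 in all, was 2977, 2965 and 2433 without untreated replicates 2, 3 and 4, and 2894 without treated replicate 4. In the tables of untreated replicates 1 and 2 the viral genes are spelled differently from the other 6, so these may form a processing batch that holds untreated cells alone. Among the other 6 libraries 594 genes were higher and 1336 lower. That fit has only 2 untreated libraries, so a gene that misses the threshold there need not have lost its change.

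Treated replicate 1 carried much of the largest rises. ARC stood at 0.105 ± 0.0959 CPM in untreated and 35.2 ± 58.8 CPM in treated libraries (SD, n = 4 each). FOS stood at 0.478 ± 0.521 CPM in untreated and 51.9 ± 76.9 CPM in treated libraries (SD, n = 4 each). The log2 fold changes were 8.32 ± 1.34 for ARC, 6.73 ± 1.12 for FOS and 6.09 ± 0.76 for ID2 (adjusted p = 0.00146, 0.00165 and 0.000491). They were 5.76 ± 0.73 for IER5L, 5.72 ± 0.84 for FAM166A, 5.68 ± 1.04 for RGS16 and 5.33 ± 0.65 for SERTAD1 (adjusted p = 0.000491, 0.000834, 0.00281 and 0.0004796). ARC stood at a log2 fold change of 9.08 and 5.73 without untreated replicate 4 or treated replicate 1. FOS stood at a log2 fold change of 7.84 and 4.78 without untreated replicate 3 or treated replicate 1. ID2 stood at a log2 fold change of 4.93 without treated replicate 1. IER5L stood at a log2 fold change of 4.51 without treated replicate 1. FAM166A stood at a log2 fold change of 4.48 without treated replicate 1. RGS16 stood at a log2 fold change of 3.57 without treated replicate 1. SERTAD1 stood at a log2 fold change of 4.47 without treated replicate 1. RGS16 missed the threshold on log2(TPM + 1) (adjusted p = 0.0545). RGS16 missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.0569). FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230) and ARC (ENSG00000198576, chromosome 8, 142611044 to 142614472) are placed here on GRCh38 with GENCODE release 29, as are all genes below.

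PTER, KRCC1 and PAQR8 fell more evenly between libraries. PTER, a phosphotriesterase-related gene (ENSG00000165983, chromosome 10, 16436943 to 16513745), was at 25.2 ± 5.22 CPM in untreated and 2.01 ± 0.492 CPM in treated libraries (SD, n = 4 each). The log2 fold changes were -3.65 ± 0.31 for PTER, -3.23 ± 0.43 for KRCC1, -3.19 ± 0.304 for PAQR8 and -3.16 ± 0.51 for TEX19 (adjusted p = 0.000201, 0.000624, 0.000313 and 0.00151). Next came -3.13 ± 0.38 for TMEM229B, -3.08 ± 0.35 for ZMYM1 and -3.08 ± 0.52 for ZSWIM4 (adjusted p = 0.000491, 0.000354 and 0.00175). AC022384.1 also met the rule, with a log2 fold change of -3.52 ± 1.03 for AC022384.1 (adjusted p = 0.0252). TEX19 stood at a log2 fold change of -3.75 without treated replicate 1. AC022384.1 missed the threshold without untreated replicates 2, 3 and 4 or treated replicate 4 (log2 fold change -3.601 to -3.32, adjusted p = 0.0507, 0.0512, 0.0633 and 0.0572). AC022384.1 stood at a log2 fold change of -5.96 without treated replicate 2. AC022384.1 missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.105).

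The genes of the kinase and cyclin that the labels name as inhibited missed the threshold. CDK12 (ENSG00000167258, chromosome 17, 39461511 to 39564907) was at 109 ± 30.7 CPM in untreated and 57.2 ± 31.9 CPM in treated libraries (SD, n = 4 each). The log2 fold changes were -0.92 ± 0.38 for CDK12, -0.28 ± 0.35 for CDK13 and 0.59 ± 0.27 for CCNK (adjusted p = 0.0858, 0.571 and 0.119), CDK13 being a related kinase and CCNK the gene of cyclin K. For the parts of P-TEFb, the kinase that releases paused polymerase, they were -0.399 ± 0.37 for CDK9 and 0.99 ± 0.4003 for CCNT1 (adjusted p = 0.438 and 0.0819). HEXIM1 (ENSG00000186834, chromosome 17, 45148502 to 45152101), which holds P-TEFb inactive, rose and was at 24.7 ± 9.34 CPM in untreated and 96.6 ± 42.7 CPM in treated libraries (SD, n = 4 each). Its log2 fold change was 1.97 ± 0.397 for HEXIM1 (adjusted p = 0.00468). CDK12 passed the threshold without treated replicate 3 (log2 fold change -1.34, adjusted p = 0.0229). CCNT1 passed the threshold without treated replicate 1 (log2 fold change 1.25, adjusted p = 0.0142). HEXIM1 missed the threshold with scaling on ribosomal protein genes (adjusted p = 0.169). HEXIM1 missed the threshold on log2(TPM + 1) (adjusted p = 0.0711). HEXIM1 missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.0528). CDK12 passed with scaling on ribosomal protein genes (log2 fold change -1.94, adjusted p = 0.0183) and on log2(TPM + 1) (adjusted p = 0.0108), while CCNK turned to -0.396 with the former. CDK9 passed on log2(TPM + 1) (adjusted p = 0.0293).

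In the list of P-TEFb, 7SK particle and super elongation complex genes, 5 of 31 were higher and 3 lower, and adjusted over the list alone, 5 were higher and 3 lower. The examples were 1.92 ± 0.39 for CCNT2 and -1.51 ± 0.41 for HEXIM2 (adjusted p = 0.00473 and 0.0191). The median log2 fold change of the list was -0.054004 and the mean 0.12 (camera adjusted p = 0.827; adjusted p = 0.969 with an estimated correlation), so the signs of median and mean differed and the list did not pass. Of transcriptional kinases and cyclins 1 of 17 was higher and 1 lower, CCNT2 and CDK19, and adjusted over the list alone, 1 was higher and 0 lower. CDK19 had a log2 fold change of -1.14 ± 0.35 for CDK19 (adjusted p = 0.0312). Taking all its members, the median log2 fold change was -0.28 and the mean -0.0443 (camera adjusted p = 0.827; adjusted p = 0.969 with an estimated correlation). CDK19 missed the threshold without untreated replicates 3 and 4 or treated replicates 3 and 4 (log2 fold change -1.14 to -0.95, adjusted p = 0.0903, 0.0719, 0.0597 and 0.0707). CCNT2 missed the threshold with scaling on ribosomal protein genes (adjusted p = 0.227). CCNT2 missed the threshold on log2(TPM + 1) (adjusted p = 0.139). CCNT2 and HEXIM2 missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.0742 and 0.146).

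The HIV-1 genes gave more counts in treated cells. They were singled out after the tables were seen to hold them. Their sum was 45.99 ± 8.995 CPM in untreated and 117 ± 30.5 CPM in treated cells (SD, n = 4 each). All 4 treated libraries lay above all 4 untreated ones (exact permutation test, two-sided, p = 0.0286, the smallest this design can give). The log2 fold changes that passed were 1.15 ± 0.28 for HIV-1 env, 1.69 ± 0.32 for HIV-1 nef and 2.26 ± 0.47 for HIV-1 rev (adjusted p = 0.0121, 0.00348 and 0.00564). Those that did not were 1.09 ± 0.48 for HIV-1 gag, 0.804 ± 0.54 for HIV-1 tat and 1.02 ± 0.51 for HIV-1 vpu (adjusted p = 0.105, 0.277 and 0.1501), and pol held 1 count and vif and vpr 0 over all libraries. The viral genes overlap and share exons, so the split of reads between them is uncertain. The rise of the sum rested on the scaling. Its log2 ratio was 1.33 with TMM factors, 0.64 in the deposited TPM (exact permutation p = 0.0571) and 0.26 with scaling on ribosomal protein genes (exact permutation p = 0.543). Without untreated replicates 1 and 2 it was 1.03 (exact permutation p = 0.0667, the smallest possible there). HIV-1 env, HIV-1 nef and HIV-1 rev missed the threshold with scaling on ribosomal protein genes (adjusted p = 0.909, 0.342 and 0.117). HIV-1 env and HIV-1 nef missed the threshold on log2(TPM + 1) (adjusted p = 0.509 and 0.0566). HIV-1 env, HIV-1 nef and HIV-1 rev missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.135, 0.0557 and 0.0626). HIV-1 gag, HIV-1 tat and HIV-1 vpu turned to -0.01904, -0.35 and -0.0305 with scaling on ribosomal protein genes.

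**Figure D1:**
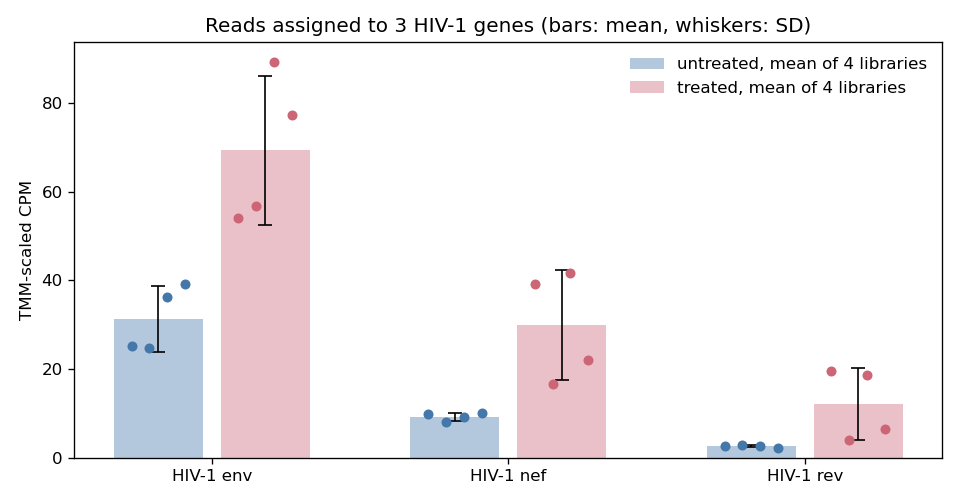
TMM-scaled CPM (vertical axis) of HIV-1 env, HIV-1 nef and HIV-1 rev in untreated and treated libraries, where points are libraries, bars group means and whiskers SDs (n = 4 each). All treated points lie above the untreated ones, with means of 31.3 and 69.3 for HIV-1 env, a difference that missed the threshold with scaling on ribosomal protein genes.

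Of the 26 gene lists 21 had at least 5 tested members, and 9 of these passed camera with its preset correlation of 0.01. With an estimated correlation 0 passed (lowest adjusted p = 0.324), and 1 had an unadjusted p under 0.05. By fry, which asks only whether the members of a list move 1 way, 5 passed. These were the DNA damage response, DNA replication, G2 and mitosis, T cell receptor and host repressor lists. Without untreated replicates 1 and 2 the medians were -1.11 for DNA damage response, -0.37 for replication, -0.59 for mitosis, 1.74 for immediate early, 2.57 for histone, 1.42 for ribosomal protein, 1.75 for mitochondrial, -0.47 for T cell receptor and -0.2996 for host repressor genes. Among lists that did not pass, scaling on ribosomal protein genes turned the medians to -0.38 for T cell activation, -0.82 for integrated stress, -0.59 for splicing, -0.74 for heat shock and -0.57 for cholesterol synthesis genes.

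In the list of DNA damage response and homologous recombination genes more were lower than higher. There 0 of 44 were higher and 26 lower, and adjusted over the list alone, 0 were higher and 29 lower. BRCA1, a gene of repair by homologous recombination (ENSG00000012048, chromosome 17, 43044295 to 43170245), was at 75.9 ± 6.01 CPM in untreated and 18.5 ± 5.05 CPM in treated libraries (SD, n = 4 each). The log2 fold changes were -2.04 ± 0.28 for BRCA1, -2.25 ± 0.32 for ATRIP and -2.17 ± 0.31 for FANCF (adjusted p = 0.000648, 0.000764 and 0.000794), ATRIP being the partner of the ATR kinase and FANCF a Fanconi anaemia gene. The median log2 fold change of the list was -1.11 and the mean -0.98 (camera adjusted p = 1.77e-09; adjusted p = 0.324 with an estimated correlation).

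Of DNA replication genes 1 of 47 was higher and 14 lower, and adjusted over the list alone, 2 were higher and 16 lower. The examples were -2.35 ± 0.29 for ORC2, -2.43 ± 0.34 for GINS1, -1.71 ± 0.24 for WDHD1 and 1.07 ± 0.25 for ORC6 (adjusted p = 0.000491, 0.0006696, 0.0007405 and 0.0103). Its members had log2 fold changes whose median was -0.41 and the mean -0.54 (camera adjusted p = 0.000646; adjusted p = 0.564 with an estimated correlation). Of genes of G2 and mitosis 2 of 39 were higher and 12 lower, and adjusted over the list alone, 2 were higher and 12 lower. ESPL1 is the gene of separase and AURKB that of Aurora kinase B. The log2 fold changes were -1.82 ± 0.26 for ESPL1, -1.51 ± 0.26 for AURKB, -1.63 ± 0.296 for NDC80 and 1.17 ± 0.304 for UBE2C (adjusted p = 0.000803, 0.00185, 0.0025999 and 0.0161). Over the list the median log2 fold change was -0.49 and the mean -0.53 (camera adjusted p = 0.000744; adjusted p = 0.564 with an estimated correlation). UBE2C missed the threshold without untreated replicates 2, 3 and 4 (log2 fold change 1.06 to 1.09, adjusted p = 0.0537, 0.05103 and 0.0582). ORC6 and UBE2C missed the threshold with scaling on ribosomal protein genes (adjusted p = 0.865 and 0.853). ORC6 and UBE2C missed the threshold on log2(TPM + 1) (adjusted p = 0.667 and 0.283). ORC6 and UBE2C missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.0959 and 0.0551). The G2 and mitosis list missed the threshold without treated replicates 1 and 4 (adjusted p = 0.0857).

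Most genes of the immediate early list, which respond to stimuli without new protein synthesis, were higher. In this list 21 of 32 were higher and 0 lower, and adjusted over the list alone, 24 were higher and 0 lower. The examples were 3.31 ± 0.43 for DUSP5, 2.45 ± 0.34 for IER2 and 3.16 ± 0.44 for JUNB (adjusted p = 0.000568, 0.0006696 and 0.000683). Its members had log2 fold changes whose median was 1.88 and the mean 2.13 (camera adjusted p = 1.57e-11; adjusted p = 0.564 with an estimated correlation). With scaling on ribosomal protein genes the median was 0.72. Treated replicate 1 stood apart from the other treated libraries for FOS, EGR2 and EGR3 of this list and had the shortest fragments (166 bases), and without it the list median was 1.42. By fry the list did not pass (adjusted p = 0.0506). JUNB stood at a log2 fold change of 2.47 without treated replicate 1.

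Most cytosolic ribosomal protein genes were higher with TMM scaling. Of these 49 of 74 were higher and 0 lower, and adjusted over the list alone, 71 were higher and 0 lower. By fry the list did not pass (adjusted p = 0.0887). The examples were 1.58 ± 0.33 for RPS7, 1.702 ± 0.36 for RPL34 and 1.61 ± 0.38 for RPL31 (adjusted p = 0.00563, 0.00567 and 0.0103). Taking all its members, the median log2 fold change was 1.12 and the mean 1.14 (camera adjusted p = 2.42e-16; adjusted p = 0.564 with an estimated correlation). RPS7, RPL34 and RPL31 missed the threshold on log2(TPM + 1) (adjusted p = 0.0769, 0.075999 and 0.184). RPL34 and RPL31 missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.0567 and 0.0756). Scaling on ribosomal protein genes sets their change near 0 and is no test of this rise. Of replication-dependent histone genes 9 of 30 were higher and 0 lower, and adjusted over the list alone, 10 were higher and 0 lower. The examples were 3.49 ± 0.58 for H4C3, 5.11 ± 0.95 for H4C15 and 3.66 ± 0.86 for H2AC17 (adjusted p = 0.00158, 0.00307 and 0.0103). Over the list the median log2 fold change was 1.07 and the mean 1.42 (camera adjusted p = 9.79e-05; adjusted p = 0.703 with an estimated correlation). The histone list did not pass by fry (adjusted p = 0.129). Histone genes have near-identical copies, so the split of reads between them is uncertain. H4C3 stood at a log2 fold change of 2.72 without treated replicate 1. H4C15 stood at a log2 fold change of 6.35 and 4.29 without untreated replicate 3 or treated replicate 1. H2AC17 stood at a log2 fold change of 4.501 and 2.53 without untreated replicate 1 or treated replicate 1. H4C15 missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.0607). With scaling on ribosomal protein genes the histone median was 0.0601.

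Of genes encoded in mitochondria 5 of 15 were higher and 0 lower, and adjusted over the list alone, 14 were higher and 0 lower. They took 0.604% of counts in untreated replicate 1, 7.04 to 12.7% in the other untreated libraries and 12.6 to 19.4% in treated ones (exact permutation test, two-sided, p = 0.0571). The examples were 2.84 ± 0.76 for MT-RNR1, 2.12 ± 0.65 for MT-ND2 and 1.75 ± 0.55 for MT-ND3 (adjusted p = 0.01799, 0.0312 and 0.0331). The median log2 fold change of the list was 1.66 and the mean 1.75 (camera adjusted p = 9.82e-07; adjusted p = 0.564 with an estimated correlation). The mitochondrial list did not pass by fry (adjusted p = 0.0711). MT-RNR1 missed the threshold without untreated replicate 3 (log2 fold change 2.57, adjusted p = 0.0566). MT-RNR1 stood at a log2 fold change of 3.59 without untreated replicate 2. MT-ND2 missed the threshold without untreated replicates 3 and 4 or treated replicates 3 and 4 (log2 fold change 1.98 to 2.08, adjusted p = 0.0848, 0.0787, 0.0656 and 0.0594). MT-ND2 stood at a log2 fold change of 2.81 without untreated replicate 2. MT-ND3 missed the threshold without untreated replicates 3 and 4 or treated replicates 3 and 4 (log2 fold change 1.56 to 1.87, adjusted p = 0.0941, 0.0628, 0.0685 and 0.06503). MT-RNR1, MT-ND2 and MT-ND3 missed the threshold with scaling on ribosomal protein genes (adjusted p = 0.0906, 0.2403 and 0.433). MT-ND2 and MT-ND3 missed the threshold on log2(TPM + 1) (adjusted p = 0.0732 and 0.122). With scaling on ribosomal protein genes the median was 0.51.

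T cell genes moved both ways. Of genes of the T cell receptor and its proximal signalling 3 of 38 were higher and 11 lower, and adjusted over the list alone, 4 were higher and 11 lower. The examples were -2.13 ± 0.296 for UBASH3A, -1.62 ± 0.24 for GRAP2, -1.701 ± 0.301 for LCP2 and 1.38 ± 0.32 for TRBC2 (adjusted p = 0.0006696, 0.000852, 0.00227 and 0.0103), TRBC2 being a constant gene of the receptor. The median log2 fold change of the list was -0.33 and the mean -0.31 (camera adjusted p = 0.0472; adjusted p = 0.564 with an estimated correlation). The list missed the threshold without treated replicate 2 or 4 (adjusted p = 0.08103 and 0.116) and with RLE factors (adjusted p = 0.0509). It also missed it with the replicate number as a block, as given below. Of T cell activation genes 5 of 14 were higher and 0 lower, and adjusted over the list alone, 6 were higher and 3 lower. The examples were 3.27 ± 0.81 for EGR3, 1.34 ± 0.35 for ICOS and 3.81 ± 0.99 for EGR2 (adjusted p = 0.0129, 0.0157 and 0.01598). Taking all its members, the median log2 fold change was 0.74 and the mean 0.8001 (camera adjusted p = 0.216; adjusted p = 0.703 with an estimated correlation), which did not pass. EGR3 stood at a log2 fold change of 2.04 without treated replicate 1. ICOS missed the threshold without untreated replicate 4 (log2 fold change 1.295, adjusted p = 0.0546). EGR2 missed the threshold without untreated replicate 4 (log2 fold change 3.49, adjusted p = 0.0522). EGR2 stood at a log2 fold change of 5.88 and 2.74 without untreated replicate 3 or treated replicate 1. TRBC2, EGR3, ICOS and EGR2 missed the threshold with scaling on ribosomal protein genes (adjusted p = 0.608, 0.101, 0.541 and 0.0814). TRBC2 and ICOS missed the threshold on log2(TPM + 1) (adjusted p = 0.162 and 0.429). TRBC2, EGR3, ICOS and EGR2 missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.0501, 0.106, 0.111 and 0.125).

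NF-kappaB targets and interferon-stimulated genes did not pass as lists. Of the former 3 of 23 were higher and 4 lower, and adjusted over the list alone, 3 were higher and 4 lower. The examples were -1.56 ± 0.27 for TNFAIP8, -1.57 ± 0.34 for NFKBIE, -1.37 ± 0.32 for TRAF2 and 2.42 ± 0.52 for CCL5 (adjusted p = 0.00227, 0.00678, 0.0102 and 0.00661). Over the list the median log2 fold change was -0.205 and the mean -0.0997 (camera adjusted p = 0.539; adjusted p = 0.828 with an estimated correlation). Of the latter 3 of 39 were higher and 7 lower, and adjusted over the list alone, 2 were higher and 7 lower. The examples were -2.205 ± 0.28 for DDX58, -1.86 ± 0.27 for IFI16, -1.43 ± 0.35 for IFIH1 and 1.53 ± 0.32 for IRF7 (adjusted p = 0.000491, 0.000819, 0.0124 and 0.00527), DDX58 and IFIH1 being sensors of RNA. Its members had log2 fold changes whose median was -0.19 and the mean -0.19 (camera adjusted p = 0.333; adjusted p = 0.768 with an estimated correlation). CCL5 and IRF7 missed the threshold with scaling on ribosomal protein genes (adjusted p = 0.126 and 0.401). CCL5 and IRF7 missed the threshold on log2(TPM + 1) (adjusted p = 0.0702 and 0.0757). NFKBIE, TRAF2, CCL5 and IFIH1 missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.0576, 0.0689, 0.0715 and 0.0572).

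Host genes that repress HIV-1 transcription had more falls than rises, as did all tested protein-coding genes (1094 higher and 2329 lower of 12980). Of these 1 of 30 was higher and 8 lower, and adjusted over the list alone, 2 were higher and 9 lower. The examples were -2.103 ± 0.24 for MORC2, -2.62 ± 0.35 for TASOR, -1.74 ± 0.26 for SETDB1 and 0.67 ± 0.23 for HDAC3 (adjusted p = 0.000408, 0.000615, 0.000977 and 0.0489), the first 3 being tied to silencing by the HUSH complex and HDAC3 being a histone deacetylase. The median log2 fold change of the list was -0.23 and the mean -0.42 (camera adjusted p = 0.0406; adjusted p = 0.564 with an estimated correlation). The list missed the threshold without treated replicate 1 or 4 (adjusted p = 0.0976 and 0.0545). HDAC3 missed the threshold without untreated replicates 1, 2, 3 and 4 or treated replicates 1, 2, 3 and 4 (log2 fold change 0.56 to 0.72, adjusted p = 0.0629, 0.0846, 0.12003, 0.156, 0.115, 0.0613, 0.08496 and 0.108). HDAC3 missed the threshold with scaling on ribosomal protein genes (adjusted p = 0.476, log2 fold change turned to -0.37 for HDAC3). HDAC3 missed the threshold on log2(TPM + 1) (adjusted p = 0.698, log2 fold change turned to -0.12 for HDAC3). HDAC3 missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.0961).

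**Figure D2:**
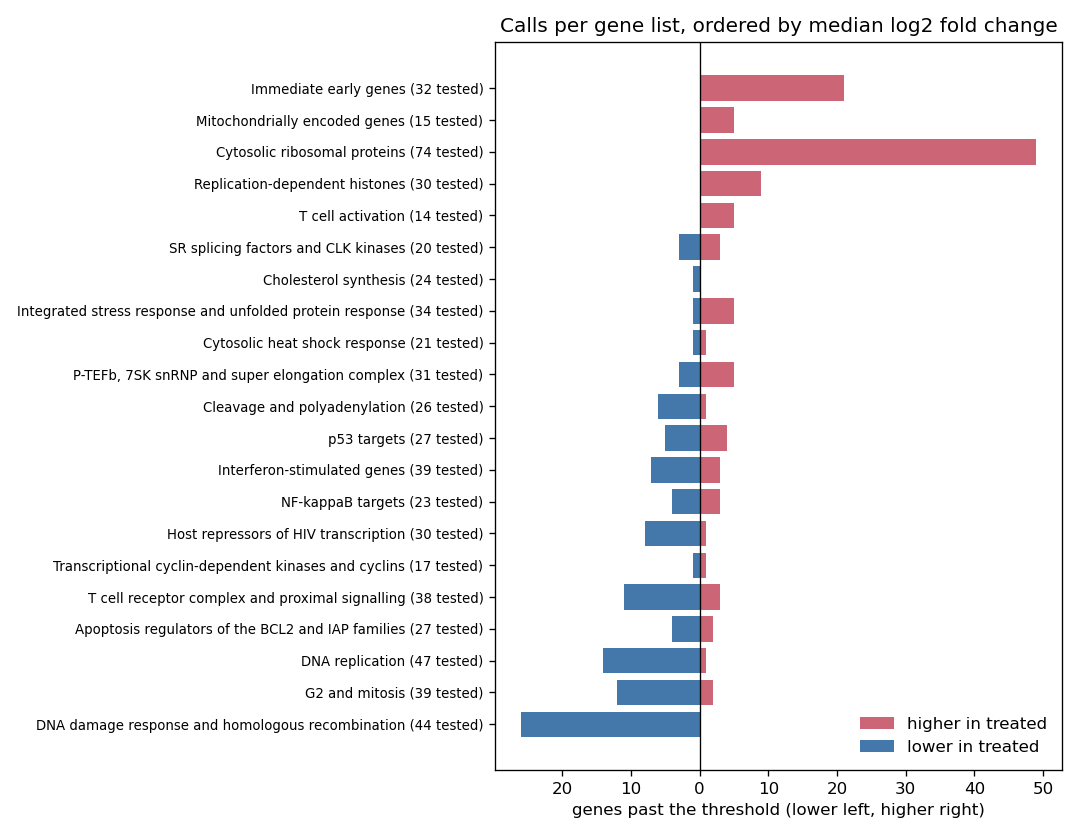
Number of genes past the threshold with TMM scaling (horizontal axis, lower in treated cells to the left, higher to the right) in the 21 lists with at least 5 tested members, ordered by median log2 fold change. The DNA damage list holds 26 lower and 0 higher genes, and the ribosomal protein list 49 higher and 0 lower, with a median near 0 where the scaling rests on those genes.

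Lists of stress and cell death genes did not pass. Of integrated stress and unfolded protein response genes 5 of 34 were higher and 1 lower, and adjusted over the list alone, 5 were higher and 1 lower. The examples were 2.36 ± 0.32 for SESN2, 1.52 ± 0.37 for CEBPG, 0.89 ± 0.24 for CRELD2 and -1.301 ± 0.41 for SEL1L (adjusted p = 0.000645, 0.0119, 0.0186 and 0.0332). Taking all its members, the median log2 fold change was 0.297 and the mean 0.37 (camera adjusted p = 0.0976; adjusted p = 0.703 with an estimated correlation). This list passed without untreated replicate 4 (adjusted p = 0.04105) or treated replicate 4 (adjusted p = 0.0117). CRELD2 missed the threshold without untreated replicates 3 and 4 (log2 fold change 0.82 to 0.83, adjusted p = 0.05601 and 0.0711). SEL1L missed the threshold without untreated replicates 3 and 4 or treated replicates 1 and 4 (log2 fold change -1.21 to -1.08, adjusted p = 0.0799, 0.101, 0.0509 and 0.0885). CEBPG and CRELD2 missed the threshold with scaling on ribosomal protein genes (adjusted p = 0.478 and 0.777, log2 fold change turned to -0.16 for CRELD2). CEBPG and CRELD2 missed the threshold on log2(TPM + 1) (adjusted p = 0.332 and 0.864). CEBPG, CRELD2 and SEL1L missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.106, 0.0726 and 0.0542). Of p53 targets 4 of 27 were higher and 5 lower, and adjusted over the list alone, 5 were higher and 6 lower. SESN2 was the rise named there, and the falls were -1.67 ± 0.26 for POLH, -1.62 ± 0.25 for XPC and -1.21 ± 0.33 for TNFRSF10B (adjusted p = 0.00109, 0.00117 and 0.0203). The median log2 fold change of the list was -0.18 and the mean 0.0796 (camera adjusted p = 0.967; adjusted p = 0.977 with an estimated correlation), with a direction of the test that was down like the median and unlike the mean. Of apoptosis regulators 2 of 27 were higher and 4 lower, and adjusted over the list alone, 2 were higher and 4 lower. The examples were -1.42 ± 0.25 for BCL2L1, -1.23 ± 0.31 for DIABLO, -1.604 ± 0.47 for APAF1 and 1.22 ± 0.26 for PMAIP1 (adjusted p = 0.00214, 0.0145, 0.0247 and 0.00618). Its members had log2 fold changes whose median was -0.35 and the mean -0.28 (camera adjusted p = 0.333; adjusted p = 0.768 with an estimated correlation). TNFRSF10B missed the threshold without untreated replicate 3 or treated replicate 4 (log2 fold change -1.099 to -1.09, adjusted p = 0.0581 and 0.0571). APAF1 missed the threshold without untreated replicates 3 and 4 or treated replicates 3 and 4 (log2 fold change -1.62 to -1.28, adjusted p = 0.083998, 0.0573, 0.0562 and 0.0541). PMAIP1 missed the threshold with scaling on ribosomal protein genes (adjusted p = 0.836). PMAIP1 missed the threshold on log2(TPM + 1) (adjusted p = 0.3404). TNFRSF10B, DIABLO and PMAIP1 missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.0544, 0.1197 and 0.0839).

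RNA processing lists did not pass either. Of cleavage and polyadenylation genes 1 of 26 was higher and 6 lower, and adjusted over the list alone, 1 was higher and 8 lower. The examples were -1.43 ± 0.24 for CSTF3, -1.505 ± 0.28 for WDR33, -1.35 ± 0.31 for CPSF2 and 1.32 ± 0.304 for CLP1 (adjusted p = 0.0016995, 0.003101, 0.00928 and 0.00926). Over the list the median log2 fold change was -0.0621 and the mean -0.197 (camera adjusted p = 0.395; adjusted p = 0.922 with an estimated correlation). Of SR splicing factor and CLK kinase genes 3 of 20 were higher and 3 lower, and adjusted over the list alone, 4 were higher and 3 lower. The examples were 1.505 ± 0.37 for CLK1, 1.08 ± 0.32 for TRA2B, 0.98 ± 0.31 for SRSF2 and -1.68 ± 0.303 for SRPK1 (adjusted p = 0.0119, 0.0254, 0.0354 and 0.0025999). Taking all its members, the median log2 fold change was 0.42 and the mean 0.14 (camera adjusted p = 0.744; adjusted p = 0.969 with an estimated correlation). TRA2B missed the threshold without untreated replicates 1, 2 and 3 or treated replicate 3 (log2 fold change 0.83 to 1.16, adjusted p = 0.0591, 0.0502, 0.0764 and 0.0792). SRSF2 missed the threshold without untreated replicates 1, 2 and 3 or treated replicates 1, 3 and 4 (log2 fold change 0.77 to 1.09, adjusted p = 0.0795, 0.0524, 0.103, 0.0579, 0.105 and 0.0514). CLP1, CLK1, TRA2B and SRSF2 missed the threshold with scaling on ribosomal protein genes (adjusted p = 0.508, 0.445, 0.926 and 0.777, log2 fold change turned to -0.16 for SRSF2). CSTF3, CLP1, CLK1, TRA2B and SRSF2 missed the threshold on log2(TPM + 1) (adjusted p = 0.06698, 0.257, 0.306, 0.494 and 0.703). CLK1, TRA2B and SRSF2 missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.144, 0.136 and 0.141).

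Heat shock and cholesterol lists held few calls. Of cytosolic heat shock genes 1 of 21 was higher and 1 lower, and adjusted over the list alone, 0 were higher and 0 lower. The values were 0.95 ± 0.29 for HSPB1, 0.76 ± 0.34 for HSPA8, 0.64 ± 0.42 for HSPA1B and -0.87 ± 0.28 for HSPA4L (adjusted p = 0.0316, 0.1104, 0.2704 and 0.0351), where HSPA1B has a near-identical copy and is uncertain. Over the list the median log2 fold change was 0.0369 and the mean 0.04503 (camera adjusted p = 0.873; adjusted p = 0.969 with an estimated correlation). Of cholesterol synthesis genes 0 of 24 were higher and 1 lower, and adjusted over the list alone, 0 were higher and 1 lower. MVK is the gene of mevalonate kinase. The values were -2.23 ± 0.295 for MVK and -0.61 ± 0.29 for INSIG1 (adjusted p = 0.000602 and 0.135). Its members had log2 fold changes whose median was 0.34 and the mean 0.11 (camera adjusted p = 0.827; adjusted p = 0.969 with an estimated correlation). HSPB1 missed the threshold without untreated replicates 2, 3 and 4 or treated replicates 1 and 3 (log2 fold change 0.77 to 0.99, adjusted p = 0.102, 0.0613, 0.0996, 0.08003 and 0.0729). HSPA4L missed the threshold without untreated replicates 2, 3 and 4 or treated replicates 1 and 3 (log2 fold change -0.94 to -0.77, adjusted p = 0.0573, 0.0749, 0.1005, 0.0582 and 0.0726). HSPB1 missed the threshold with scaling on ribosomal protein genes (adjusted p = 0.8004, log2 fold change turned to -0.14 for HSPB1). HSPB1 missed the threshold on log2(TPM + 1) (adjusted p = 0.686). HSPB1 and HSPA4L missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.116 and 0.0641). HSPA8 and HSPA1B turned to -0.32 and -0.67 with scaling on ribosomal protein genes.

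Markers of other cell types had fewer than 5 tested members per list and were not tested as sets. The summed level was 76.97 TPM untreated and 69.7 TPM treated for B cell markers, most of it CD79A, with 0 of 3 called. For myeloid markers it was 3.8 and 7.09 TPM, with 2 of 3 higher. For NK cell markers it was 13.7 and 11.1 TPM, with 1 of 4 higher and 1 lower. For erythroid markers it was 11.7 and 9.55 TPM, with 1 of 2 higher and 1 lower. For epithelial markers it was 6.5 and 4.44 TPM, most of it CDH2, with 0 of 3 called over all genes and 2 higher when adjusted over the list alone. The log2 fold changes were 2.695 ± 0.85 for LYZ, 1.77 ± 0.604 for CD68 and 0.797 ± 0.83 for ITGAM (adjusted p = 0.0333, 0.0447 and 0.493) for myeloid genes. They were 2.82 ± 0.72 for KLRD1, 0.84 ± 0.46 for NKG7, 0.69 ± 0.58 for NCAM1 and -1.65 ± 0.41 for PRF1 (adjusted p = 0.0152, 0.186, 0.392 and 0.0126) for NK cell genes and 1.87 ± 0.56 for HBA1 and -1.47 ± 0.39 for EPOR (adjusted p = 0.0273 and 0.0169) for erythroid genes. LYZ missed the threshold without untreated replicates 2, 3 and 4 or treated replicates 1 and 4 (log2 fold change 2.402 to 2.98, adjusted p = 0.0843, 0.0639, 0.0626, 0.0642 and 0.0714). CD68 missed the threshold without untreated replicates 1, 2, 3 and 4 or treated replicates 1 and 3 (log2 fold change 0.77 to 1.91, adjusted p = 0.0656, 0.0996, 0.0894, 0.121, 0.254 and 0.0631). CD68 stood at a log2 fold change of 0.77 without treated replicate 1. KLRD1 missed the threshold without treated replicate 4 (log2 fold change 1.51, adjusted p = 0.0666). KLRD1 stood at a log2 fold change of 1.51 without treated replicate 4. HBA1 missed the threshold without untreated replicates 3 and 4 or treated replicates 1 and 3 (log2 fold change 1.56 to 1.75, adjusted p = 0.0752, 0.0823, 0.0666 and 0.0737). LYZ, CD68, KLRD1 and HBA1 missed the threshold with scaling on ribosomal protein genes (adjusted p = 0.227, 0.583, 0.0944 and 0.353). LYZ, CD68, KLRD1 and HBA1 missed the threshold on log2(TPM + 1) (adjusted p = 0.0582, 0.407, 0.276 and 0.1196). LYZ, CD68, KLRD1, PRF1, HBA1 and EPOR missed the threshold without untreated replicates 1 and 2 (adjusted p = 0.106, 0.166, 0.138, 0.0522, 0.056003 and 0.0666).

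More of the long genes were lower than of the short ones, while most long genes were not called. With all 8 libraries and the filter on low counts, the test between libraries did not pass. Of protein-coding genes under 10 kb in genomic span, 388 were higher and 264 lower of 2498, with a median log2 fold change of 0.28. Of those of 100 kb and over, 125 were higher and 630 lower of 2435, with a median of -0.42. Between 10 and 30 kb 333 were higher and 539 lower, and between 30 and 100 kb 248 and 896. With scaling on ribosomal protein genes the medians of the shortest and longest genes were -0.71 and -1.42. Per library, the median log2 CPM of genes of 100 kb and over minus that of genes under 10 kb was 0.14 ± 0.34 untreated and -0.404 ± 0.25 treated (SD, n = 4 each). The treated value minus the untreated one was -0.54 (exact permutation test, two-sided, p = 0.0857). Without untreated replicate 1, which lay among the treated libraries at -0.28, it was -0.66 (exact permutation p = 0.0286). With no filter on low counts, where genes of few counts enter, it was -1.42 (exact permutation p = 0.0286). For the genes that the filter keeps, that fit gave median log2 fold changes of 0.14 under 10 kb and -0.56 at 100 kb and over. On log2(TPM + 1) the treated value minus the untreated one was -0.0891 (exact permutation p = 0.686), on log2(TPM + 0.1) -0.198 (exact permutation p = 0.4) and on the deposited log2 values -0.12 (exact permutation p = 0.486). Without untreated replicates 1 and 2 it was -0.78 (exact permutation p = 0.0667, the smallest possible there).

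**Figure D3:**
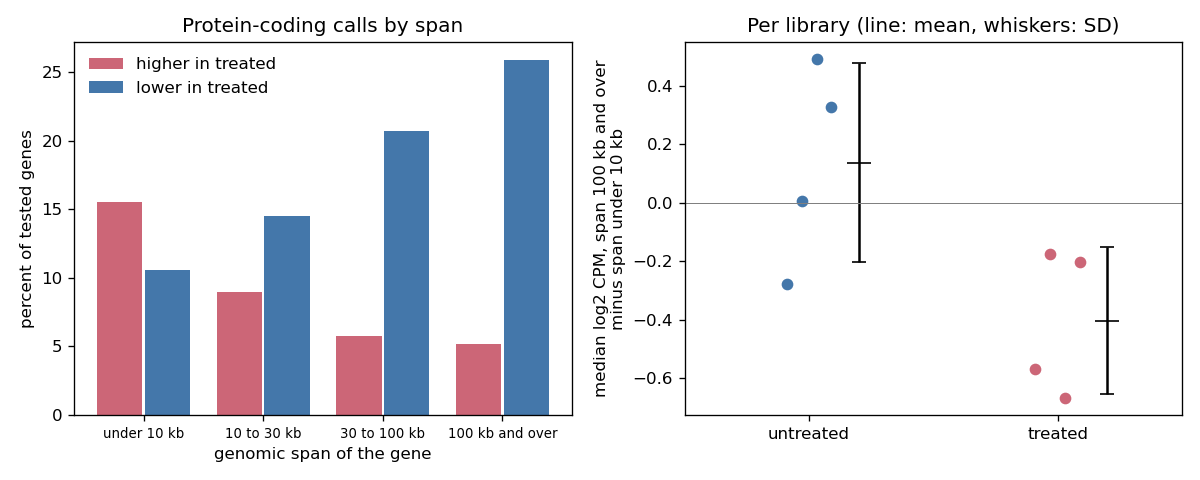
Left, percentage of tested protein-coding genes (vertical axis) that were higher or lower in treated cells with TMM scaling, by genomic span (horizontal axis). Right, median log2 CPM of genes of 100 kb and over minus that of genes under 10 kb (vertical axis) per library, with group means as lines and SDs as whiskers (n = 4 each); falls take 10.6% of the shortest and 25.9% of the longest genes, and the lowest untreated library lies among the treated ones.

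Most called long non-coding RNA (lncRNA) genes were higher with TMM scaling. Of these 605 were higher and 98 lower (86.1% higher), against 1094 and 2329 protein-coding genes (31.96% higher). The shares differed by Fisher's exact test, two-sided, across genes, which are not independent replicates (p = 3.21e-161). Pseudogenes had 113 higher and 24 lower, and small RNA genes 28 and 0. Without untreated replicates 3 and 4 or treated replicate 4 there were 77 higher and 12 lower, 65 higher and 8 lower, and 73 higher and 15 lower pseudogenes. Without untreated replicates 1, 3 and 4 or treated replicate 4 there were 73 higher and 0 lower, 18 higher and 0 lower, 12 higher and 0 lower, and 11 higher and 0 lower small RNA genes. Small RNA calls were 3 higher and 0 lower without treated replicates 1 and 4, and 58 and 0 without untreated replicate 1 and treated replicate 4. With scaling on ribosomal protein genes 22 pseudogenes were higher and 89 lower, and 4 small RNA genes were higher and 0 lower. Pseudogenes share sequence with their parent genes and are uncertain. Of called lncRNA genes that overlap no protein-coding gene 88.5% were higher, and of those that overlap one 84.1%. The strand setting of the counting is not given in the sources used here, so reads of overlapping genes cannot be separated. With scaling on ribosomal protein genes the direction turned, with 82 lncRNA genes higher and 273 lower, while the share of higher genes stayed above that of protein-coding genes (23.1 and 2.28%, Fisher p = 2.95e-47). Treated replicate 4 had a count for 43795 genes, against 23313 to 28804 in the other libraries. Without it 310 lncRNA genes were higher and 84 lower. Without treated replicates 1 and 4 there were 196 and 101, and without untreated replicates 1 and 2 128 and 57. The number of higher lncRNA genes was 355, 397 and 291 without untreated replicates 2, 3 and 4.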

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

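The tests of treatment as a source of the genes detected in treated replicate 4, of span slopes per library and the gap between their groups, of the bootstrap interval of matched genes and of fits without 2 libraries were chosen after the results were seen. Of 236 groups of 4 values examined, 18 had 1 library far from the other 3, against about 11.8 by chance, and 9 of these libraries were treated replicate 1.

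Treated replicate 4 had a count for 43795 genes, against 25734 to 28804 in the other treated libraries, and 9097 of 22127 genes at 0 elsewhere had a count there, together 0.07903% of its counts. RNA of another cell type is argued against by the listed markers under 1 TPM elsewhere, of which CD22 was highest at 3.92 TPM. Treatment as the whole cause is argued against by the other treated libraries, which detected 24782, 25699 and 28804 genes at equal depth, the last above and the others under the highest untreated library at 26686, against 43435 in treated replicate 4. Genomic DNA or unspliced RNA is a candidate source, since counts of these genes rose with exonic length (Spearman rho = 0.592 across genes, which are not independent) and 82.9% of 181 olfactory receptor genes among them had a count, against 72.4% of other protein-coding ones. This source stays open.

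Of genes of 100 kb and over, 630 were lower and 125 higher of 2435. With all 8 libraries and the filter on low counts, the difference between libraries did not pass its test. Exonic length, GC content and expression level are argued against as the whole cause, although the difference between libraries by exonic length was -0.64 (exact permutation p = 0.171), since 98.3% of the slope of log2 fold change on log10 genomic span was left with them in the model (from -0.39 to -0.39, 95% interval -0.43 to -0.34 over genes, which are not independent). The difference between groups in slopes per library was -0.41 without these terms (exact permutation p = 0.0857) and -0.37 with them (exact permutation p = 0.0286). With them, a single library as the cause is argued against by a gap of 0.243 between the groups, wider than the range within either, at most 0.2001. The slopes ran over 0.137 to 0.224 untreated and -0.306 to -0.106 treated. Each slope is relative to the mean over the 8 libraries, so the opposite signs of the groups are built in. They do not show that levels rose with span in untreated cells. For the difference in medians, without these terms, a single library and a difference between groups cannot be told apart, since the groups overlapped in 7 of 8 sets with 1 library left out and overlap with all 8 too, although it stayed negative at -0.66 to -0.41. Inhibition of CDK12 stays open and untested, as does the transform of the values, with differences of -0.0891, -0.198 and -0.12 on log2(TPM + 1), log2(TPM + 0.1) and the deposited log2 values.

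More called lncRNA genes were higher than lower. Background in treated replicate 4 as the whole cause is argued against, since 78.7% were higher without it. The 95% Wilson interval, 74.4 to 82.4%, is over genes, which are not independent. Without treated replicates 1 and 4 the share was 65.99%. Called protein-coding genes matched on expression level and span were higher in 66.003% of cases (95% bootstrap interval 60.4 to 71.7%, also over genes), against 86.1% of lncRNA genes. The matched share lay just past the bound of 20 percentage points below the lncRNA share, a bound set before the result was seen. Class on the one hand and level and span on the other still cannot be told apart, since the bootstrap interval, chosen afterwards, holds that bound. Treatment stays open, as does the scaling for the direction alone, since scaling on ribosomal protein genes lowers both shares by construction, and 23.1% of called lncRNA genes were higher there against 2.28% of protein-coding ones.

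Untreated replicate 1 had a count for 23313 genes, against 26625 to 27293 in the other untreated libraries. Treated replicate 1 stood apart from the other treated libraries at 123 CPM for ARC (others 2.34 to 10.4), 167 CPM for FOS (others 5.199 to 21.3), 342 CPM for ID2 (others 47.4 to 77.8), 364 CPM for IER5L (others 25.2 to 78.7), 25.5 CPM for RGS16 (others 0.779 to 2.37), 5.86 CPM for EGR3 (others 0.723 to 1.03), 5.36 CPM for EGR2 (others 0.828 to 1.09), 1.55 CPM for ITGAM (others 0.0834 to 0.331) and 12.6 CPM for NKG7 (others 4.18 to 4.92). Treated replicate 2 stood apart at 3.45 CPM for AC022384.1 (others 0 to 0.563), and treated replicate 4 at 11.6 CPM for KLRD1 (others 1.06 to 2.51). Among untreated libraries, replicate 1 stood apart at 3.07 CPM for IER5L (others 2.22 to 2.33) and 20.1 CPM for UBE2C (others 11.5 to 12.4). Untreated replicate 3 stood apart at 1.26 CPM for FOS (others 0.1999 to 0.252) and 0.474 CPM for EGR2 (others 0.0229 to 0.0444), and untreated replicate 4 at 84.9 CPM for BRCA1 (others 72.1 to 73.7).

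Across the 35 splits of the 8 libraries into 4 and 4, 1 gave as many changed genes as the split by treatment. This was that split itself, with 4488 genes against 0 in the highest other. Every other split mixes treated and untreated libraries, which widens the spread within its groups. For the number of genes these splits therefore cannot exclude chance, and neither can a rank of 1 in 35. For gene lists chance cannot be excluded, since 15 of the 35 splits gave at least the 9 lists of the split by treatment and the highest other gave 13.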

How the results depend on the processing

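The fits without 2 libraries, on the deposited log2 values and all of the HIV-1 sum, and lncRNA calls scaled on ribosomal protein genes, were chosen after the data were seen. In no fit did a gene called with TMM scaling pass in the opposite direction. With 1 library left out, 2433 to 4927 genes changed, 913 to 2347 were higher and 1520 to 2580 lower. Without untreated replicates 1 and 2, 1930 changed, 594 higher and 1336 lower. Without untreated replicate 1 and treated replicate 4 the numbers were 2955, 1329 and 1626, and without treated replicates 1 and 4 3009, 1154 and 1855. At an adjusted p under 0.01 they were 1462, 454 and 1008. DESeq2 gave 6854 changed, 3980 higher and 2874 lower. Scaled on ribosomal protein genes 243 were higher and 5113 lower, on log2(TPM + 1) 380 and 5286, and on log2(TPM + 0.1) 400 and 5288. By construction the ribosomal protein scaling moves every gene by about the same amount and sets its reference genes near 0, so it tests neither the ribosomal protein list nor its genes, though the numbers of alternatives below include these. The causes of the other differences were not tested. Lists past the threshold numbered 14 of 26 with no filter, all 14 among the 21 also tested with it, 0 of 21 with an estimated correlation and 8 to 10 with 1 library left out. The span difference passed at -1.42 with no filter, where genes of few counts enter, and, with the filter, at -0.66 without untreated replicate 1 (exact permutation p = 0.0286 for each). It ran over -0.66 to -0.41 with 1 library left out. By exonic length of the tables it was -0.64, at 30 kb and over against under 30 kb -0.34 and for genes of at least 10 CPM -0.69 (exact permutation p = 0.171, 0.0571 and 0.0571). It shrank to -0.0891 on log2(TPM + 1), -0.198 on log2(TPM + 0.1) and -0.12 on the deposited log2 values (exact permutation p = 0.686, 0.4 and 0.486). The HIV-1 sum had a log2 ratio of 1.16 to 1.47 with 1 library left out. It missed the threshold at 0.26 scaled on ribosomal protein genes and 0.64 on TPM. At 1.03, 1.29 and 1.27 without untreated 1 and 2, treated 1 and 4, and untreated 1 and treated 4, the groupings were too few to pass. The share of higher genes among lncRNA calls ran over 78.7 to 89.5% with 1 library left out.

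The replicate numbers showed no clear pairing of the libraries, as same-numbered libraries had deviations that correlated at 0.15, -0.11, -0.1995 and 0.0748. With 4 libraries per group, these correlations cannot exclude a pairing. With the replicate block 3785 genes changed, 1501 higher and 2284 lower, 8 lists passed and 80.8% of lncRNA calls were higher. The T cell receptor list missed the threshold there (adjusted p = 0.0618), and the median of p53 targets, which had not passed, was -0.26. Exact sign flips of the 4 same-numbered differences, which cannot go below p = 0.125, gave -0.54 for span and 1.33 for the HIV-1 sum.

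Lists whose test turned direction had not passed, and their medians were as follows. With 1 library left out the values ran over -0.36 to 0.0252 for p53, -0.299 to 0.0126 for P-TEFb, -0.13 to 0.18 for heat shock, -0.0334 to 0.43 for cholesterol, -0.54 to -0.0875 for transcriptional kinases and 0.00587 to 0.54 for splicing. Scaled on ribosomal protein genes the medians were -1.06 for P-TEFb, -0.74 for heat shock and -0.57 for cholesterol. With no filter the medians were -0.14 for P-TEFb, -0.0676 for heat shock, 0.31 for splicing and 0.197 for cholesterol. At 1 CPM in 4 libraries the medians were -0.197 for transcriptional kinases and -0.0932 for p53. Without treated 1 and 4 the medians were 0.15 for transcriptional kinases, -0.16 for p53 and 0.18 for polyadenylation. Without untreated 1 and treated 4 the medians were 0.0825 for transcriptional kinases and 0.13 for p53. With DESeq2 the medians were -0.196 for p53. On log2(TPM + 1) the medians were -0.7001 for P-TEFb, -0.77 for heat shock, -0.79 for p53 and -0.49 for cholesterol. On log2(TPM + 0.1) the medians were -0.81 for P-TEFb, -0.87 for heat shock, -0.94 for p53 and -0.53 for cholesterol. On the deposited log2 values the medians were -0.102 for heat shock. With members of no other list the medians were -0.13 for P-TEFb. Of the other alternatives of lists, 381 kept the direction of the test and the side of the threshold, 27 lost the call and 13 gained it. In some of these the median alone turned, in lists that had not passed. Genes turned as follows, none of them past the threshold once turned. With 1 library left out the values ran over -0.7003 to 1.14 for ITGAM. Without treated 1 and 4 the log2 fold changes were 0.15 for CDK13, -1.36 for ITGAM and -0.39 for NCAM1. Scaled on ribosomal protein genes the log2 fold changes were -0.396 for CCNK, -0.14 for HSPB1, -0.32 for HSPA8, -0.67 for HSPA1B, -0.16 for CRELD2, -0.16 for SRSF2, -0.37 for HDAC3, -0.63 for ITGAM, -0.23 for NKG7, -0.57 for NCAM1, -0.01904 for HIV-1 gag, -0.35 for HIV-1 tat and -0.0305 for HIV-1 vpu. On log2(TPM + 1) the log2 fold changes were -0.25 for CCNK, -0.11 for HSPA8, -0.26 for HSPA1B, -0.12 for HDAC3, -0.00528 for ITGAM, -0.0143 for NCAM1 and -0.0528 for HIV-1 tat. On log2(TPM + 0.1) the log2 fold changes were -0.26 for CCNK, -0.00243 for CCNT1, -0.11 for HSPA8, -0.31 for HSPA1B, -0.12 for HDAC3, -0.14 for NCAM1 and -0.0453 for HIV-1 tat. Without untreated 1 and treated 4 the log2 fold changes were 0.16 for CDK9. Of the other alternatives of the genes followed, 1846 kept direction and side of the threshold, 271 lost the call and 17 gained it. The causes were not tested beyond the scaling. Most 2-fold changes were missed in simulated data of this depth and spread. There only 200 genes were changed at fixed folds and 85 were called, against 4488 calls in the real data. Fewer calls make the adjusted threshold stricter, so this rate does not carry over to the real fit.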

Other observations

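The test of genes named ZNF and the choice of pathways named here were made after the data were seen. By the pathways given in the deposited log2 table, 31 of 121 oxidative phosphorylation genes were higher and 3 lower in treated cells (camera adjusted p = 3.18e-07; adjusted p = 0.926 with an estimated correlation), with a median log2 fold change of 0.71, less than the shift of the ribosomal protein scaling. Of Hedgehog signalling genes 1 of 42 was higher and 16 lower (camera adjusted p = 0.00539; adjusted p = 0.926 with an estimated correlation). Of Fanconi anaemia pathway genes 1 of 53 was higher and 24 lower (camera adjusted p = 0.000764; adjusted p = 0.926 with an estimated correlation), and some of these genes are also in the DNA damage list. Of 335 pathways 23 passed camera with a correlation of 0.01 and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. These were homologous recombination, the Fanconi anaemia pathway and non-homologous end-joining (camera with an estimated correlation, unadjusted p = 0.00318, 0.00658 and 0.0369). In homologous recombination 0 of 41 genes were higher and 19 lower, and in end-joining 0 of 13 were higher and 4 lower.

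Treated cells may hold slightly shorter isoforms of the same genes. The median log2 ratio of the isoform-weighted length of a gene to its mean over libraries, over 8361 protein-coding genes, was 0.0127 ± 0.00339 untreated and -0.00958 ± 0.0109 treated (SD, n = 4 each). It was lower in 4 of 4 treated libraries than in every untreated one, by a difference of -0.0222 (exact permutation test, two-sided, p = 0.0286, the smallest possible). The values rest on the authors' estimates of isoform levels. Treated replicate 1 had the lowest value, -0.0246, and also the shortest fragments.

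Of 450 tested genes named ZNF, 43 were higher and 102 lower, with a median log2 fold change of -0.28. As a set they did not pass against other genes (camera with an estimated correlation, unadjusted p = 0.429).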
